A study of Homo sapiens with 24 samples.

How the data were processed

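RNA from human CD4+ CD25- CD45RO+ memory T cells was sequenced in 24 libraries, 3 in each of 8 groups. Per the labels, thawed cells in serum-free medium received medium alone (control), IL-17A at 10 ng/ml, IL-17F at 10 ng/ml, or IL17A + IL17F at 10 ng/ml each, before stimulation through CD3 and CD28, and were harvested after 48 or 168 h. The authors demultiplexed the reads with bcl2fastq and quantified transcripts with kallisto on GRCh38. The versions of both tools and the annotation release are not given in the sources used here.

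The deposited table of each library holds, per transcript, the estimated count of reads, with no normalisation. A further deposited column holds TPM (length-normalised transcript abundance), computed by the authors' kallisto run. Each table lists 173259 transcripts. Of these, 159239 were matched to a gene by identifier in GENCODE 29, 11235 by gene symbol, and 2785 had no gene there. The transcripts matched by identifier held 96.4% to 96.9% of the counts of a library. Estimated counts were summed over the transcripts of a gene and rounded, which gave 34092 genes. Genes on the Y chromosome, XIST and TSIX were not used, which removed 117 genes with counts, so that no sex can be read from the values. Coordinates are those of GENCODE 29 on GRCh38, and symbols were updated by gene identifier.

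The labels give no donor, culture or replicate number. Replicates were numbered in the order of the listing. The library numbers in the titles form 6 runs of 4 consecutive numbers, and each run holds all 4 conditions at 1 time. For 8 libraries at 168 h the number in the file name differs from that in the title. Groups were taken from the titles and characteristics. The sample labels name IL-17A and IL-17F side by side, while the series text speaks of IL-17AF, so the combination could be a mixture or the heterodimer.

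Counts were tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1). Genes were kept by filterByExpr on the 8 groups, which left 16224. Libraries were scaled by TMM, with factors of 0.903 to 0.950 at 48 h and 1.01 to 1.15 at 168 h. A robust quasi-likelihood model of the 8 group means was fitted to all 24 libraries, with 16 residual degrees of freedom and a common biological coefficient of variation of 0.279. P-values were two-sided and were adjusted by the Benjamini-Hochberg method over all genes tested. A gene passed at an adjusted p under 0.05, with no minimum fold change. In all, 18 comparisons were made: 168 h against 48 h in each condition and in their mean, each cytokine against control at each time, the mean of the 3 cytokine groups against control at each time, IL-17A against IL-17F, the combination against the mean of the single cytokines, and the change of the cytokine effect between times. Values per group are TMM-scaled CPM (counts relative to the library total), given as mean and SD of 3 libraries. Fold changes are on the log2 scale, with the standard error (SE) of the model.

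Sets of genes were tested with camera on log2 CPM (prior count 2, preset inter-gene correlation 0.01), adjusted over 35 lists written from general knowledge before the data were examined. Lists needed at least 5 tested genes, and 1 list gene had no match. The lists cover IL-17 receptor signalling, stromal targets of IL-17, T-cell activation and costimulation, IL-2 and STAT5 targets, NF-kB targets, immediate-early and heat-shock genes, Th1, Th2, Th17, Tfh and Treg genes, cytotoxic genes, chemokine and homing receptors, inhibitory receptors, TGF-beta targets, quiescence and memory genes, interferon-response genes, G1/S and G2/M cell-cycle genes, replication histones, p53 and apoptosis genes, the unfolded protein response, the integrated stress response, glycolysis, oxidative phosphorylation, cholesterol synthesis, ribosome biogenesis, mitochondrially encoded genes, and markers of naive CD4 T cells, CD8 T and NK cells, gamma-delta T and MAIT cells, B cells, monocytes and dendritic cells, red cells and platelets, and epithelial or stromal cells. Camera compares a list with the other genes. It was repeated with an estimated correlation and with fry, which tests whether the genes of a list move on balance in 1 direction without comparing them with other genes.

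Genes named in the text follow a rule fixed before the data were examined: IL17RA, IL17RC, TRAF3IP2, IL17A and IL17F throughout; for time in the controls, the 12 largest rises and 12 largest falls among genes that passed, had an average log2 CPM of at least 4 and showed no overlap between groups; for a cytokine comparison in which no gene passed, the 3 rising and 3 falling genes with the smallest p and an average log2 CPM of at least 2; and from each called list the 2 to 4 members with the largest fold change, or the smallest p where none passed. HLA genes and T-cell receptor and immunoglobulin segments were not named, and some genes that the rule picks are not reported here. Other genes named were chosen after their values were seen.

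Alternatives planned before the data were examined were no count filter, an average CPM of at least 5, a minimum absolute log2 fold change of 1, counts rebuilt from TPM scaled by gene length, DESeq2 size factors, DESeq2 1.42.0 (Wald test), limma-voom, fits on the compared groups alone, the number range of the titles as a covariate, removal of the 8 libraries with disagreeing numbers, removal of each replicate in turn, and a block for the run. The block leaves 12 residual degrees of freedom and a coefficient of variation of 0.0932. For time, where each run lies at 1 time, the run was a random term in limma-voom (correlation 0.636). Chosen after seeing the data were a block that joins runs of the same order at both times, a within-run permutation of list means, removal of replicate 3 of all 8 groups, removal of IL17F_48h replicate 2, and thinning of the 48 h libraries to the depth of those at 168 h.

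The pipeline was tested on simulated data. Each model was tested on its own counts, simulated from its own fit to these libraries. Those for the model without the block held no difference between runs, and those for the block did. The shares therefore do not compare the 2 models on the same counts, and those without the block leave out the correlation within runs. For IL-17A against control at 48 h, 83.3% of 2-fold changes in genes with a log2 CPM of at least 4 were recovered without the block and 100% with it. For 1.5-fold changes these shares were 5.41% and 83.8%. Of the calls, 2.74% were false without the block and 6.08% with it. For time in the control cells, without a block, 69.2% of 2-fold changes in such genes were recovered and 9.09% of the calls were false. For genes with a log2 CPM of at least 4, counting error is small at these depths (18078246 to 29188035 estimated counts per library), and the spread between libraries sets the precision.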

Results

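Gene expression was measured by RNA sequencing in activated human memory CD4+ T cells, sorted as CD4+ CD25- CD45RO+, with and without cytokines of the IL-17 family. IL-17A and IL-17F are secreted by a subset of helper T cells and signal through a receptor built from IL17RA and IL17RC. The 24 libraries form 8 groups of 3: control, IL-17A, IL-17F and IL17A + IL17F, each after 48 h and after 168 h of stimulation through CD3 and CD28. Libraries held 22835150 to 29188035 estimated counts at 48 h and 18078246 to 21802298 at 168 h. Within a run of 4 consecutive library numbers, the control total differed from the mean of the cytokine totals by at most 6.35%. After filtering, 16224 genes were tested. Time was the largest source of variation, and the first principal component held 53.6% of the variance. Libraries of the same time also grouped by run. After removal of the group means, the 36 pairs of libraries from the same run correlated at r of 0.479 to 0.705 across genes, and the 72 pairs from other runs at -0.445 to -0.0809. Runs of the same order at the 2 times correlated at 0.460 to 0.501 in all 3 pairs, against -0.309 to -0.205 in the 6 others. All 24 libraries were closest to their own run, so counts of genes with the run as a block are given for the cytokine comparisons.

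**Figure D1:**
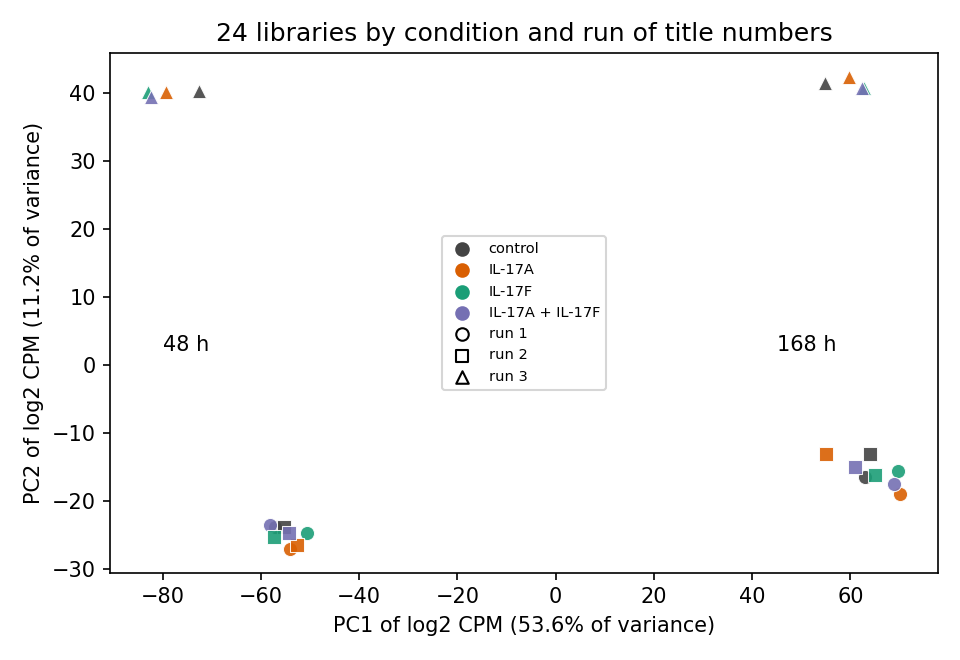
Principal components 1 (53.6% of the variance) and 2 (11.2%) of log2 CPM, unitless scores, with a point per library, colours for the 4 conditions and marks for time and run. Component 1 parts the 12 libraries at 48 h from the 12 at 168 h, and the 4 conditions of a run lie together. Component 2 parts run 3 from runs 1 and 2, which overlap in this plot.

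Whether memory T cells can receive an IL-17 signal depends on the receptor, so its genes were examined first. IL17RA (ENSG00000177663, chromosome 22, 17084954 to 17115694) was expressed at 55.8 ± 1.33 CPM (SD, n = 3) in control cells at 48 h and 56.7 ± 10.8 at 168 h, a log2 fold change of 0.02 ± 0.12 (SE, adjusted p = 0.902). IL17RC (ENSG00000163702, chromosome 3, 9917074 to 9933630), the second chain, was low at 1.10 ± 0.171 and 0.956 ± 0.128 CPM. TRAF3IP2 (ENSG00000056972, chromosome 6, 111556454 to 111606278), which encodes the adaptor ACT1, rose from 19.3 ± 1.48 to 31.5 ± 6.08 CPM (log2 fold change 0.71 ± 0.17, adjusted p = 0.00231), but did not pass without the 8 libraries whose numbers disagree (0.52, adjusted p = 0.0602). IL17F itself (ENSG00000112116, chromosome 6, 52236681 to 52244537) fell from 33.6 ± 30.3 to 1.23 ± 0.719 CPM, a log2 fold change of -4.77 ± 1.11 (adjusted p = 0.00184). IL17A (ENSG00000112115, chromosome 6, 52186375 to 52190638) had 20.8 ± 22.1 and 7.14 ± 3.98 CPM, and its change of -1.54 ± 1.03 did not pass (adjusted p = 0.237). In the mean of the 4 conditions, IL17RC (-0.57 ± 0.21, adjusted p = 0.0230) and IL17A (-1.18 ± 0.51, adjusted p = 0.0434) fell. With the run as a random term in limma-voom neither passed (adjusted p = 0.261 for IL17RC and 0.224 for IL17A). IL17A was also lost without replicate 1 of any group at 48 h, or without replicate 2 or 3 of any group at 168 h (adjusted p = 0.0548 to 0.128). IL17RC was lost without IL17F_48h replicate 2 (adjusted p = 0.0708), IL17A_168h or IL17F_168h replicate 1, or replicate 2 of the control, IL-17F or IL17A + IL17F groups at 168 h (0.0528 to 0.0582). None of the 5 genes passed in a comparison of cytokine with control at either time. IL17RA, for example, differed from control by -0.01 ± 0.12 with IL-17A at 48 h and by -0.15 ± 0.12 at 168 h, both with an adjusted p of 1. IL17RC was low, and IL17A and IL17F varied between control libraries at 48 h about as much as their means. Large changes of these 3 genes could thus have gone undetected.

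**Figure D2:**
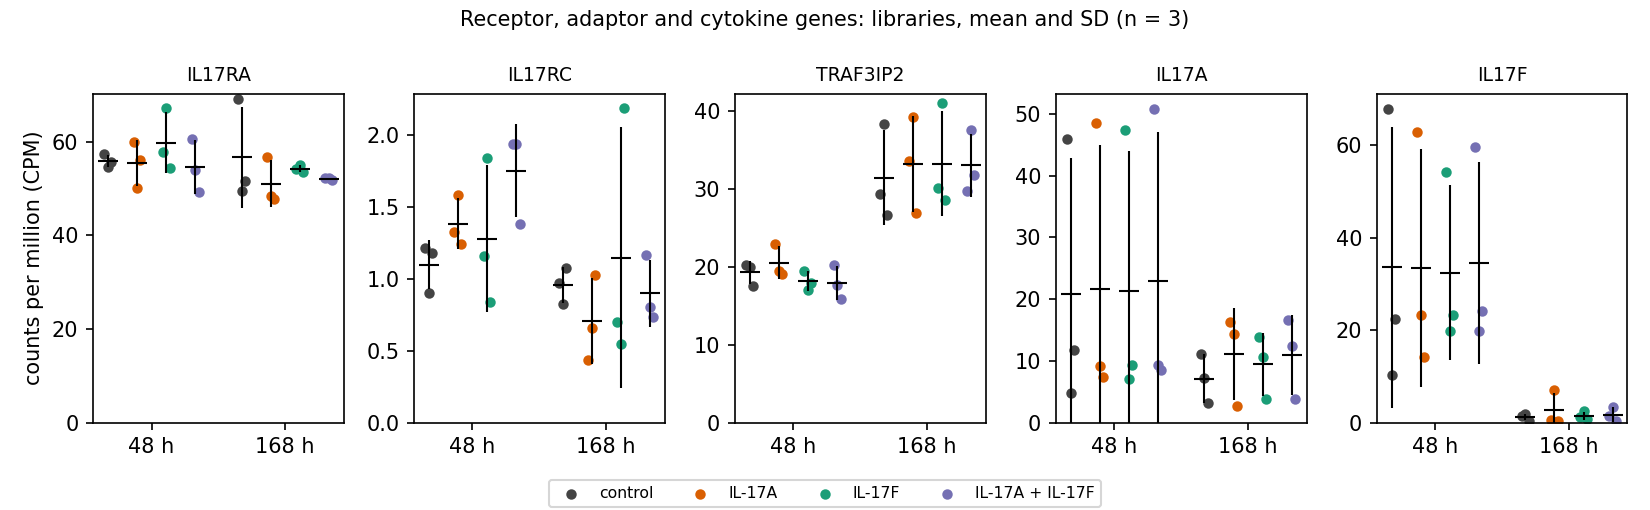
Expression of IL17RA, IL17RC, TRAF3IP2, IL17A and IL17F in CPM by condition and time, with a point per library and a bar for the mean ± SD of 3 libraries, the lower arm stopping at 0 where the SD exceeds the mean. Group means lie at 51.0 to 59.8 CPM for IL17RA and at 0.708 to 1.75 CPM for IL17RC, and IL17F is lower at 168 h in all 4 conditions.

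The 2 control groups show how the cells changed between 48 and 168 h of activation without added cytokine. In control cells 3112 genes rose and 4025 fell, 7137 of 16224 in edgeR, against 7395 in DESeq2, 7161 in limma-voom and 7103 with the run as a random term. A block that joins runs of the same order at both times, chosen after seeing the data, gave 9049, with 7134 of the 7137 among them. At an unadjusted p under 0.05 there were 8275. APOD, a lipocalin (ENSG00000189058, chromosome 3, 195568702 to 195584205), had the largest rise, from 0.189 ± 0.165 to 48.9 ± 26.9 CPM (log2 fold change 7.89 ± 0.67, adjusted p = 3.68e-08). The phosphatase gene PTPN3 rose by 5.19 ± 0.38. RAB37, SHC4, DTHD1, ATP9A, ZC3H12C, MYO18B and DLG5 rose by 4.12 to 4.75. Among genes of cytotoxic granules, GNLY (chromosome 2, 85685175 to 85698854) rose from 39.0 ± 20.9 to 768 ± 243 CPM (4.30 ± 0.62, adjusted p = 1.81e-05) and GZMK (chromosome 5, 55024253 to 55034570) from 7.16 ± 3.08 to 145 ± 94.5 CPM (4.34 ± 0.89, adjusted p = 6.58e-04). Among genes that fell were those of cytokines. IL9 (chromosome 5, 135892246 to 135895827) went from 96.7 ± 56.6 to 0.158 ± 0.198 CPM (-9.11 ± 0.97, adjusted p = 6.10e-07), and IL10 (chromosome 1, 206767602 to 206772494) from 118 ± 64.4 to 1.86 ± 1.44 CPM (-5.96 ± 0.71, adjusted p = 2.27e-06). IL3 fell by 3.39 ± 0.77, but did not pass without the 8 libraries whose numbers disagree (adjusted p = 0.116). FOXP3, the regulatory T-cell factor, which activated human T cells also express, fell from 76.4 ± 17.3 to 10.5 ± 1.20 CPM (-2.86 ± 0.29, adjusted p = 2.75e-07). IDO1, the nuclear import gene IPO4, the kinase gene NME1, the polyamine gene ODC1, RRS1, the chaperone gene HSPE1 and PIGW fell by 2.84 to 3.75. The rule for naming required that each of these genes lay beyond the other time in 3 of 3 libraries, so this is no separate result.

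Lists of growth and metabolism were among those that fell. All 35 ribosome-biogenesis genes tested fell, 35 of 35 also adjusted over the list alone, with a median log2 fold change of -1.83. NCL, which encodes nucleolin, went from 2448 ± 41.3 to 498 ± 54.4 CPM (-2.30 ± 0.14), and BOP1, NOP16 and MRTO4 fell by 2.28 to 2.53. The list was called by camera (adjusted p = 5.50e-21), but not on its own estimate, with adjusted p = 0.228 with an estimated correlation. Of 35 G1/S genes 33 fell and 0 rose (34 adjusted over the list alone, median -1.35, camera adjusted p = 9.15e-13, against adjusted p = 0.481 with an estimated correlation), led by UHRF1 (-2.36 ± 0.22). Of 36 oxidative-phosphorylation genes 28 fell (28 adjusted over the list alone, median -0.72, camera adjusted p = 4.82e-10, against adjusted p = 0.228 with an estimated correlation), among them CYCS for cytochrome c (-2.02 ± 0.15) and NDUFAB1 (-1.65 ± 0.17). In the unfolded protein response 16 of 24 fell (16 adjusted over the list alone, camera adjusted p = 5.21e-05), with SDF2L1 at -2.04 ± 0.23 and DNAJB11 at -1.33 ± 0.24. In the integrated stress response 16 of 30 fell and 2 rose (19 and 3 adjusted over the list alone, camera adjusted p = 0.00168), and the serine synthesis gene PSAT1 fell by 2.48 ± 0.34. CBS, the list's largest fall (-2.69 ± 0.90, adjusted p = 0.0208), did not pass without control_48h replicate 1 (adjusted p = 0.200), control_168h replicate 1 (0.0781) or control_168h replicate 3 (0.0806). These last 2 lists had an adjusted p = 0.481 with an estimated correlation.

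The lists of NF-kB targets and of IL-2 and STAT5 targets also held more falls than rises. Of 29 NF-kB targets 16 fell and 2 rose (the same counts adjusted over the list alone, median -0.72, camera adjusted p = 0.0151), led by LTA, which encodes lymphotoxin (-2.70 ± 0.30), and TNFAIP2 (-2.43 ± 0.66; adjusted p = 0.0571 without replicate 3 of all groups). Of 21 targets of IL-2 and STAT5, 12 fell and 1 rose (12 and 1 adjusted over the list alone, median -0.79, camera adjusted p = 0.0151), with the feedback inhibitor CISH at -2.35 ± 0.44 and MYC at -2.21 ± 0.23. Both lists had an adjusted p = 0.481 with an estimated correlation. In cholesterol synthesis 11 of 24 genes fell and 1 rose (11 and 1 adjusted over the list alone, camera adjusted p = 0.0151, against adjusted p = 0.641 with an estimated correlation), led by ACAT2 (-1.73 ± 0.22). In glycolysis 10 of 24 fell (10 adjusted over the list alone, camera adjusted p = 0.0281, against adjusted p = 0.648 with an estimated correlation). LDHA fell by 1.79 ± 0.30 and PGAM1 by 1.26 ± 0.33 (adjusted p = 0.0728 without replicate 3 of all groups). In the other direction, 11 of 27 genes of quiescence and memory rose and 2 fell (11 and 2 adjusted over the list alone, median 0.48, camera adjusted p = 0.0280, against adjusted p = 0.481 with an estimated correlation). KLF2, a factor of resting T cells, rose by 3.13 ± 0.69 and TSC22D3 by 2.93 ± 0.36, followed by TXNIP (2.58 ± 0.38). Camera thus called 10 of 35 lists with the preset correlation, 0 with an estimated one, and fry 21. Without replicate 1 at both times, the lists for cholesterol synthesis (adjusted p = 0.0629), glycolysis (0.138) and quiescence (0.0831) were not called.

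**Figure D3:**
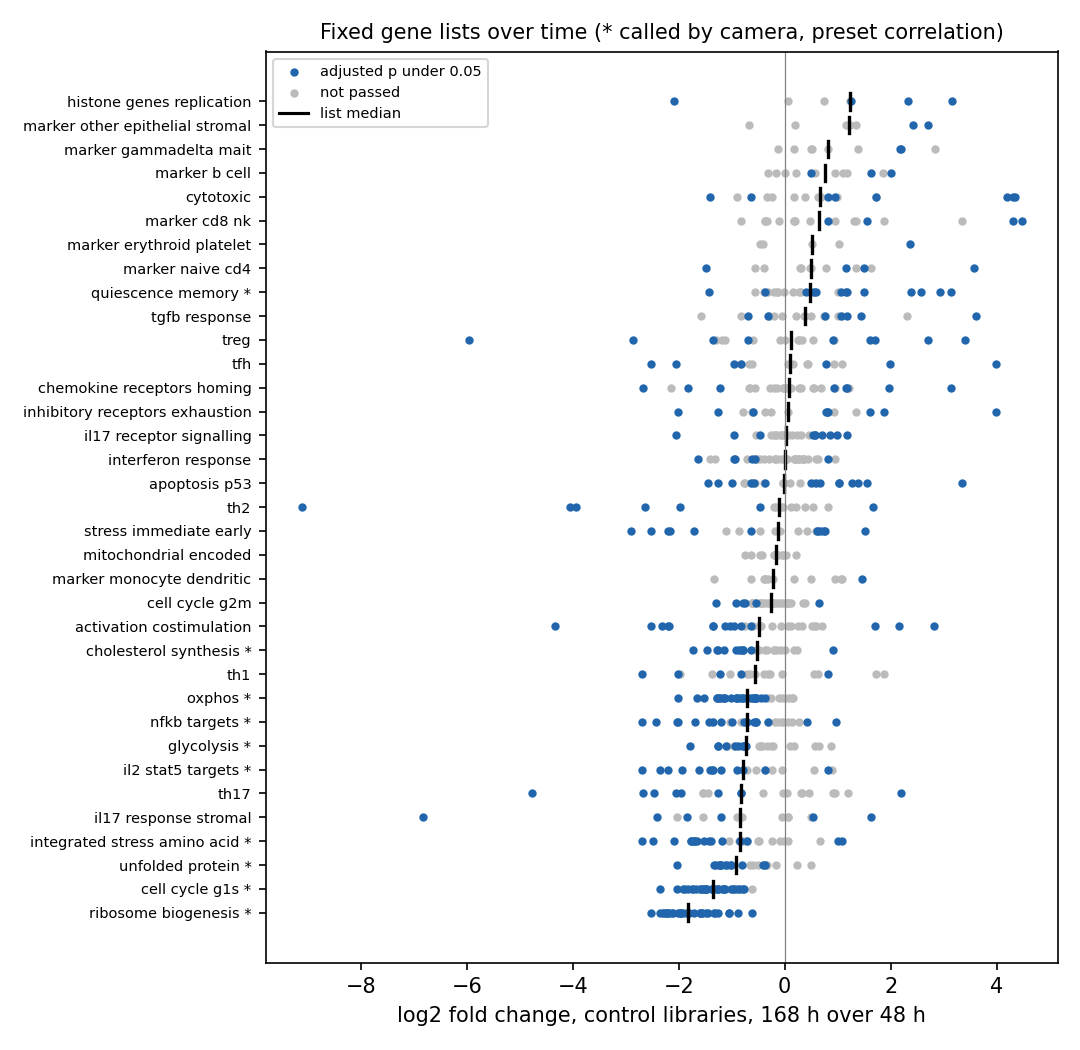
Log2 fold change, 168 h against 48 h, in the control cells for each gene of the 35 lists, with a point per gene (blue where it passed), a black line at the list median and an asterisk at lists called by camera. Ribosome biogenesis (median -1.83) and G1/S genes (-1.35) lie furthest below 0.

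More Th1, Th2, Th17 and activation genes fell than rose, Treg and Tfh genes went both ways, and none of these lists was called. Members of lists that were not called were chosen for naming after their values were seen. Of 16 Th2 genes 6 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.272), among them IL4 (-4.06), IL13 (-3.93) and IL5 (-2.63) beside IL9. Of 21 Th17 genes 8 fell and 1 rose, also adjusted over the list alone (0.274), with CCR6 at -2.67 and IL1R1 at -2.46. Of 19 Th1 genes 4 fell and 1 rose, also adjusted over the list alone (0.200). TBX21 fell by 1.22, while IFNG, at -1.98, did not pass (adjusted p = 0.0752). Of 20 Treg genes 5 rose and 4 fell, also adjusted over the list alone (0.965), with LAYN up by 3.4. Of 16 Tfh genes 3 rose and 4 fell, also adjusted over the list alone (0.584). Of 29 activation and costimulation genes 12 fell and 3 rose, also adjusted over the list alone (0.165). IL2 fell by 4.33 and CD40LG by 2.53, while CD38 rose by 2.82. Immediate-early and heat-shock genes split, with 6 up and 6 down of 20, also adjusted over the list alone (0.272), as HSPH1 fell by 2.53 and HSPD1 by 2.21 while DUSP1 rose by 1.51. Of 17 inhibitory receptor genes 6 rose and 3 fell (7 and 3 adjusted over the list alone, 0.290), with TOX2 up by 3.99 and CD160 down (-2.01). Of 21 TGF-beta targets 5 rose and 2 fell, also adjusted over the list alone (0.176). In the p53 and apoptosis list 9 rose and 6 fell of 27, also adjusted over the list alone (0.539), and TP53INP1 rose by 3.35. Of 28 chemokine and homing receptor genes 5 rose and 3 fell (0.539), of 32 G2/M genes 1 rose and 5 fell (0.193), and of 13 mitochondrially encoded genes 0 passed (0.584), with the same counts adjusted over the list alone. Of 7 replication histone genes 3 rose and 1 fell (4 and 1 adjusted over the list alone, 0.165). Of 36 interferon-response genes 1 rose and 5 fell (0 and 3 adjusted over the list alone, 0.732). Median and mean of the fold changes differed in sign for the Treg (0.13 and -0.13), p53 and apoptosis (-0.02 and 0.14), interferon (8.59e-04 and -0.13) and monocyte and dendritic lists (-0.22 and 0.12).

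Genes of IL-17 signalling and of other cell types were read in the same way. Of 25 IL-17 receptor signalling genes 7 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.441), with TRAF5 up by 0.99 beside TRAF3IP2 and HSP90AA1 down (-2.05). Of 14 stromal targets of IL-17, 2 rose and 4 fell (2 and 5 adjusted over the list alone, 0.389). CXCL8 rose by 1.63 and ICAM1 fell by 1.20. IL6 had no counts in the 3 control libraries at 168 h against 0.619 ± 0.429 CPM at 48 h, at least 4.41-fold lower with a floor of 3 counts per library, and the list median stays at -0.85 with IL6 at that bound. Of 18 cytotoxic genes 6 rose and 2 fell, also adjusted over the list alone (0.0904). FGFBP2 rose by 4.20 ± 0.45 beside GNLY and GZMK, whereas GZMB fell from 4719 ± 1680 to 1776 ± 913 CPM (-1.41). Of 18 CD8 and NK markers 4 rose (3 adjusted over the list alone, 0.149), namely GNLY, KLRD1 (0.83), KLRC2 (4.47) and CD8A, which reached 2.03 ± 0.874 CPM. CD4 stood at 431 ± 85.8 and 485 ± 82.6 CPM. Of 13 naive CD4 markers 3 rose and 1 fell, also adjusted over the list alone (0.200), with SOX4 up by 3.57. Few markers of other cells passed: 3 of 12 for B cells (1 adjusted over the list alone, 0.187), 2 of 9 for gamma-delta T and MAIT cells (1 adjusted over the list alone, 0.165), 1 of 13 for monocytes and dendritic cells (1 adjusted over the list alone, 0.539), 1 of 5 for red cells and platelets (1 adjusted over the list alone, 0.539) and 2 of 8 for epithelial or stromal cells (2 adjusted over the list alone, 0.165), all upward.

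Cells kept with cytokine changed with time much as the controls did. With IL-17A 7168 genes passed (3114 up, 4054 down; 8330 at an unadjusted p under 0.05), with IL-17F 7718 (3451 up, 4267 down) and with IL17A + IL17F 7664 (3419 up, 4245 down). DESeq2 called 7462, 7994 and 7946, limma-voom 7277, 7797 and 7698, and the run as a random term 7257, 7642 and 7618. In the mean of the 4 conditions 11796 genes passed (5870 up, 5926 down), and 8450 with the run as a random term. The balance of rises and falls depended on the scaling. With DESeq2 size factors in edgeR 6306 rose and 5575 fell in the mean, and in control 3416 rose and 3670 fell. The block joining runs of both times gave 9064 genes with IL-17A, 9567 with IL-17F, 9578 with IL17A + IL17F and 12805 in the mean. In all 4 conditions 2343 genes rose and 3490 fell, and 3 passed in opposite directions. Control and IL-17A cells shared 2592 risen genes (597 if independent) and 3672 fallen genes (1006 if independent). IL17F fell in each condition, by 3.69 ± 1.03 with IL-17A, 4.46 ± 1.09 with IL-17F and 4.31 ± 1.07 with IL17A + IL17F, and TRAF3IP2 rose by 0.70 ± 0.17, 0.87 ± 0.17 and 0.88 ± 0.17. Fitted on its own groups alone, the IL-17A fall of IL17F did not pass (adjusted p = 0.0663). Camera called 8 lists with IL-17A, 9 with IL-17F, 9 with IL17A + IL17F and 10 in the mean, 0 of them with an estimated correlation, while fry called 22, 23, 21 and 33. The calls were lists also called in the controls, without cholesterol synthesis and glycolysis for IL-17A and without glycolysis for the other cytokine groups. Without replicate 2, 13 lists were called with IL-17A.

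Each cytokine was compared with control at 48 h to ask whether IL-17 acts on activated memory cells. No gene passed in edgeR with IL-17A, IL-17F or IL17A + IL17F. At an unadjusted p under 0.05 there were 96, 133 and 124 genes, and 349, 599 and 398 with the run block, where 811 would be expected by chance. Counts so far under 811 show that the test without the block was conservative, here and in the cytokine comparisons below. Differences between runs stayed in its spread, so the lack of passing genes does not exclude a change. The counts with the block at 48 h also lay under 811, so the blocked test may be conservative there too. The cause was not tested. DESeq2 called 2, 2 and 2 genes, limma-voom 0, 0 and 0, and the run block 0, 0 and 1. Among genes with an average log2 CPM of at least 2, those nearest to passing with IL-17A were ZNF182 (0.82), ZNF354B (0.98) and MTRNR2L10 (0.30) upward and RCN1P2 (-0.72), SLC15A2 (-0.50) and USP54 (-0.60) downward, all with an adjusted p of 1. With IL-17F they were HIVEP3 (1.6), RYR1 (2.85), GNRHR2 (0.79), FSIP2 (-0.50), TBC1D8B (-0.43) and ZMYM1 (-0.56). IL17F_48h replicate 2 lay apart from the other 3 libraries of its run, with a chi-square per degree of freedom of 49.07 to 53.76 against 3.61 to 4.12 among those. Without it 0 genes passed with IL-17F. With IL17A + IL17F they were MTRNR2L10 (0.33), ZNF182 (0.79), MTRNR2L1 (0.25), TCEA1P2, NPIPB11 (-0.87) and NLRC3 (-0.67). TCEA1P2, a pseudogene, had no counts in the 3 libraries with IL17A + IL17F against 4.38 ± 2.88 CPM in control, at least 33.3-fold lower with a floor of 3 counts per library. It passed with the run block (adjusted p = 0.0294) and in DESeq2 (3.52e-06), but 89.4% of its 31-base words occur in another gene, so its counts are uncertain. The other DESeq2 calls were PEDS1-UBE2V1 with each cytokine (adjusted p = 4.09e-09, 2.17e-08 and 8.97e-09) and RPL15P3 with IL-17A (0.00158) and IL-17F (1.28e-05), which share 99% and 89.2% of their words with other genes. Both genes had no counts in the 3 control libraries and in 2 of the 3 with IL-17F. Their calls with IL-17F thus rest on 1 library each. Without control_48h replicate 2, the histone gene H4C15 (97.2% shared) passed with IL-17A (adjusted p = 0.0492) and with IL17A + IL17F (0.0371). Of 8405 genes with a log2 CPM of at least 4, the 95% interval of the fold change lay within 2-fold for 96.3%, 96.1% and 96.4%, and for 99.7%, 99.8% and 99.8% with the block. Among the genes named as nearest to passing in the comparisons of cytokines, those that share at least 50% of their words with another gene have uncertain counts: ARPC4-TTLL3, GNRHR2, MRPL12, NPIPB11, OVCA2, PVRIG, RCN1P2, SMIM11, SNURF, SULT1A4, SUMO1P3, TCEA1P2 and ZACN.

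At the level of lists, interferon-response genes were lower with IL-17A at 48 h. All 36 genes had a negative fold change, with a median of -0.25, and camera called the list (adjusted p = 1.33e-09; with the block 1.34e-19), against adjusted p = 0.941 with an estimated correlation. The list mean was below the control of its own run in 3 of 3 runs. Of its genes 0 passed, and 0 adjusted over the list alone. STAT2 (-0.17 ± 0.10), XAF1 (-0.64 ± 0.44), IFIH1 (-0.34 ± 0.24) and CMPK2 (-0.45 ± 0.41) had the smallest p. IL-17F (median -0.17, adjusted p = 0.569) was called with the block alone (0.0155, against adjusted p = 0.969 with an estimated correlation and 0.998 in fry), and was below the control of its run in 2 of 3 runs. With IL17A + IL17F no list was called under either model. In the mean of the 3 cytokine groups 0 genes passed in edgeR (122 at an unadjusted p under 0.05, 392 with the block), 1 in DESeq2, 0 in limma-voom and 0 with the block. The interferon list had a median of -0.15 (adjusted p = 0.00145, against adjusted p = 0.984 with an estimated correlation) and was lost without replicate 3 (0.418). The red-cell and platelet list, with 5 genes and a median of -0.59 (0.0408, against adjusted p = 0.238 with an estimated correlation), was lost with the block (0.176) and without replicate 1 (0.292) or 3 (0.563). TUBB1 (-0.67 ± 0.45) and HBA1 had the smallest p. HBA1 stood at 0.208 CPM in control and at 0.0603, 0.0427 and 0 CPM with IL-17A, IL-17F and IL17A + IL17F, near the floor of 3 counts per library, so no fold is given.

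Named genes of that mean were ZNF182, MTRNR2L10 and GBAP1 upward and TCEA1P2, LRIG2 and HTN1 downward, all with an adjusted p of 1. Neither list of IL-17 biology was called at 48 h. With IL-17A, IL-17F and IL17A + IL17F the receptor signalling genes had medians of -0.03, -0.03 and -1.09e-04 (camera adjusted p = 0.840, 0.945 and 0.849) and the stromal targets 0.04, 0.01 and 0.12 (0.999, 0.994 and 0.660). With IL17A + IL17F the mean of the stromal targets was above the control of its own run in 3 of 3 runs (0.116, 0.114 and 0.129, with a camera adjusted p of 0.224 with the block). The runs were mixed with IL-17A (0.14, 0.00944 and -0.13) and IL-17F (0.0531, -0.0497 and -0.0187).

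At 168 h the same comparisons were made after longer exposure. Again 0 genes passed in edgeR with IL-17A (113 at an unadjusted p under 0.05), IL-17F (111) or IL17A + IL17F (0.647% of the 16224 genes). With the block 797, 740 and 795 genes had an unadjusted p under 0.05, near the 811 expected by chance. DESeq2 called 1, 0 and 0 genes, limma-voom 0, 0 and 0, and the run block 2, 0 and 0. IL2, the T-cell growth factor (chromosome 4, 122451470 to 122456725), was nearest to passing with IL-17A, at 1.86 ± 0.917 against 0.636 ± 0.247 CPM in control (log2 fold change 1.55 ± 0.43, adjusted p = 1; with the block 1.52, adjusted p = 0.321). It stood at 1.44 ± 0.569 CPM with IL17A + IL17F (1.18 ± 0.43) and at 0.664 ± 0.168 with IL-17F. CYP20A1 (0.50), TPM1 (0.41), OVCA2 (-0.54) and MIEN1 (-0.37) were next with IL-17A. With IL-17F they were FSIP2 (0.45), VARS2 (2.52), SUMO1P3 (0.55), MRPL12 (-0.67), ZACN (-1.42) and PDF (-1.39). With IL17A + IL17F they were VARS2 (3.59), SUMO1P3 (0.71), SLC15A4 (-0.45), MACROD1 (-0.72) and PVRIG (-0.52) beside IL2. GUSBP9, a pseudogene with 94% of its words in other genes, had 0.266 ± 0.418 CPM with IL-17A against 3.14 ± 1.62 in control. It passed in DESeq2 (adjusted p = 0.0114), with the block (0.0458) and without IL17A_168h replicate 3 (0.0153). Without the 8 libraries whose numbers disagree, GTF2H2B (97.2% shared) passed with IL-17F (adjusted p = 0.00107). Intervals lay within 2-fold for 95.8%, 96.1% and 95.9% of the 8405 genes, and for 99.6% in each case with the block.

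Interferon-response genes were lower with each cytokine at 168 h. The medians were -0.42 with IL-17A, -0.30 with IL-17F and -0.35 with IL17A + IL17F, with 35 of 36 genes below 0 in each case. Camera called the list in all 3 (adjusted p = 2.00e-11, 5.73e-06 and 1.74e-08), against adjusted p = 0.898, adjusted p = 0.989 and adjusted p = 0.997 with an estimated correlation. The call with IL-17F was lost without replicate 1 (0.246). Of the 36 genes 0 passed, and 0 adjusted over the list alone. The list mean was below the control of its own run in 2 of 3 runs with IL-17A and in 3 of 3 with IL-17F and with IL17A + IL17F. The 3 comparisons share the same control libraries, so they are not independent. With IL-17A, IL-17F and IL17A + IL17F the difference was -0.855, -0.717 and -0.714 in run 1. It was 0.0704, -0.157 and -0.0162 in run 2, and -0.672, -0.166 and -0.475 in run 3. In run 1, where the difference was largest, the control library lay apart from the 3 cytokine libraries (chi-square per degree of freedom 14.65 to 20.15, against 6.35 to 8.77 among those). EPSTI1 (ENSG00000133106, chromosome 13, 42886388 to 42992271), which interferon induces, had 30.95 ± 13 CPM in control and 17.01 ± 5.18 with IL-17A (-0.86 ± 0.38, adjusted p = 1). With the run block it passed (-0.83 ± 0.14, adjusted p = 0.0458). XAF1 (-1.07 ± 0.45; adjusted p = 0.335 with the block), PARP9 (-0.34 ± 0.16) and IRF7 (-0.77 ± 0.39) did not pass under either model. With IL-17F the members nearest to passing were IFIT2 (-0.76 ± 0.40) and PARP9 (-0.27 ± 0.16), and with IL17A + IL17F XAF1 (-0.95 ± 0.44) and EPSTI1 (-0.78 ± 0.38; adjusted p = 0.186 with the block).

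**Figure D4:**
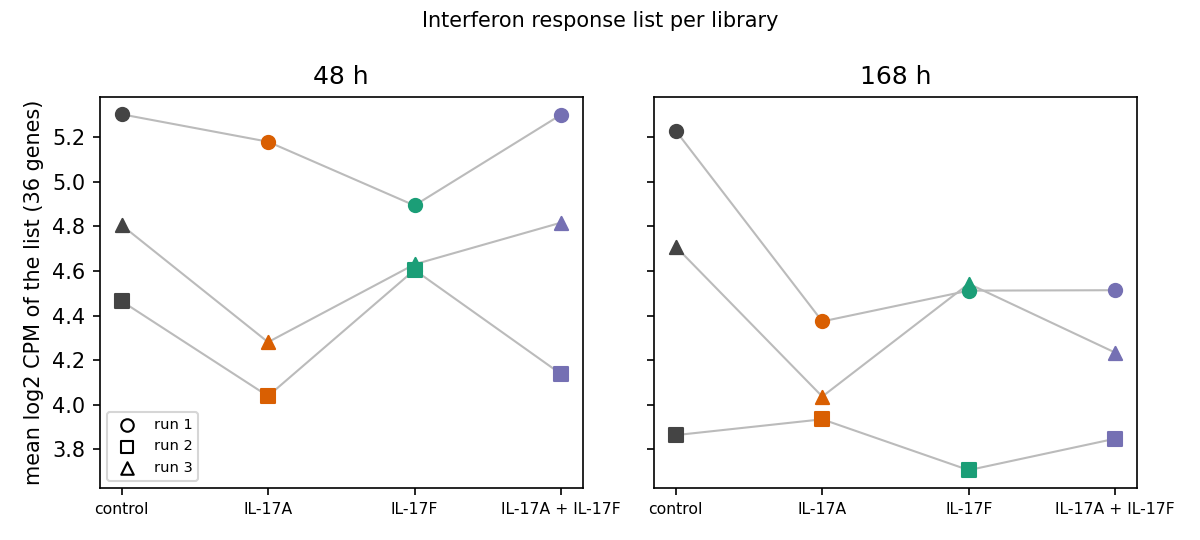
Mean log2 CPM of the 36 interferon-response genes per library, by condition at 48 and 168 h, with a point per library and lines joining the 4 libraries of a run. The mean of the 3 cytokine libraries is below the control of its run by the most in run 1 at 168 h (-0.76), and nearly level with it in run 2 (-0.03).

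In the mean of the 3 cytokine groups at 168 h 0 genes passed in edgeR (131 at an unadjusted p under 0.05, 923 with the block), 0 in DESeq2 and 0 in limma-voom. EPSTI1 alone passed with the block (-0.68 ± 0.11, adjusted p = 0.0452; without it -0.71 ± 0.29, adjusted p = 1.00) and was below the control of its run in 9 of 9 cytokine libraries. These 9 are set against only 3 control libraries, so they are not independent, and the control of run 1 lay apart from its run. GTF2H2B passed without the 8 libraries whose numbers disagree (adjusted p = 0.00769). The genes nearest to passing were VARS2 (2.46), SUMO1P3 (0.59), CYP20A1 (0.36), OVCA2 (-0.48), ZACN (-1.13) and ZNF696 (-0.59). The interferon list was called with a median of -0.38 and 36 of 36 genes below 0 (adjusted p = 5.33e-12, against adjusted p = 0.949 with an estimated correlation). Exchanging the control label within runs, 2 of 64 assignments gave a difference as large as the real one of -0.41 (exact permutation p = 0.0312, two-sided, adjusted p = 0.851 over 35 lists). At 48 h the same test gave -0.20 (exact permutation p = 0.266). The smallest p these permutations allow is 0.0156, which the 35 lists take to 0.547. Ribosome-biogenesis genes were lower with IL-17F (median -0.12, 31 of 35 below 0, adjusted p = 3.22e-05, against adjusted p = 0.989 with an estimated correlation), led by POLR1B (-0.38 ± 0.21) and NOP56 (-0.22 ± 0.13), and in the mean of the cytokine groups (-0.07, adjusted p = 0.0399, against adjusted p = 0.949 with an estimated correlation). This last call was lost without replicate 2 (0.0779) or 3 (0.589). With the block camera called 10 lists with IL-17A, 6 with IL-17F, 4 with IL17A + IL17F and 4 in the mean, in place of 1, 2, 1 and 2, and 0 with an estimated correlation. Th17 genes were among them, higher with IL-17A (median 0.17, adjusted p = 6.57e-04 with the block and 0.217 without) and with IL17A + IL17F (0.11, 0.00588 and 0.588). Relative to the control of the run, the Th17 list stood at -0.0364, 0.338 and 0.119 with IL-17A, so run 1 went the other way. With IL17A + IL17F it stood at 0.165, 0.111 and 0.0946. Receptor signalling genes had medians of 0.02, 0.04 and 0.02 (0.497, 0.622 and 0.641), and stromal targets 0.15, 0.15 and -2.52e-03 (0.327, 0.469 and 0.696). IL6 had no counts in the control libraries and lay at or under the floor of 3 counts with each cytokine; with IL6 set to no change the stromal medians were 0.105, 0.0826 and -0.00881. With IL-17A the mean of the stromal targets was above the control of its run in 3 of 3 runs (0.101, 0.184 and 0.123, with a camera adjusted p of 0.0805 with the block). The runs were mixed with IL-17F (0.096, -0.0764 and 0.177) and IL17A + IL17F (0.156, -0.157 and 0.226).

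IL-17A and IL-17F bind the same receptor with different strength, so they were compared directly. No gene passed in edgeR at 48 h (127 at an unadjusted p under 0.05, 457 with the block) or at 168 h (113, 644 with the block), and DESeq2, limma-voom and the block called 0 at both times. Without IL17A_168h replicate 3, GUSBP9 passed at 168 h (adjusted p = 0.0284). The genes nearest to passing at 48 h were MIPOL1 (0.32), ZNF354B (1.06), PIAS2 (0.24), RCN1P2 (-0.85), SNURF (-1.59) and SPX (-0.65). At 168 h they were IL2 (1.48 ± 0.43), SLC6A9 (1.40), MRPS17 (0.35), SMIM11 (-2.34), SULT1A4 (-0.61) and GDPGP1 (-0.40). The interferon list was lower with IL-17A at 48 h (median -0.11, camera adjusted p = 0.0111, against adjusted p = 0.992 with an estimated correlation), a call lost without replicate 2 (0.736), which holds the IL-17F library that lay apart from its run, or 3 (0.953). STAT2 (-0.11 ± 0.10) and IFITM1 (-0.29 ± 0.26) were nearest to passing. Relative to the control of the run, the list stood at -0.124 with IL-17A and -0.41 with IL-17F in run 1, the opposite order, against -0.426 and 0.14 in run 2 and -0.525 and -0.176 in run 3. At 168 h 6 lists were higher with IL-17A, each with adjusted p = 0.905 with an estimated correlation. They were G2/M (median 0.16, adjusted p = 0.00139, CENPA 0.26 and NDC80 0.22), the integrated stress response (0.20, 0.00139, SESN2 0.42 and PSAT1 0.43), ribosome biogenesis (0.08, 0.00290, GNL3 0.21 and POLR1B 0.27), G1/S (0.13, 0.00729, SLBP 0.12 and CLSPN 0.29), activation (0.08, 0.00928, IL2 and TNFSF14 0.40) and the unfolded protein response (0.09, 0.00928, SDF2L1 0.29 and HSP90B1 0.20). With the block camera called 13 lists, and without replicate 2 it called 2. Lost without replicate 2 were activation (adjusted p = 0.211), G1/S (0.114), the integrated stress response (0.0615), ribosome biogenesis (0.143) and the unfolded protein response (0.0615). Without replicate 3, G1/S (0.221) and the unfolded protein response (0.0612) were lost. Of the members of these lists 0 passed, and 0 adjusted over the list alone.

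The combination was set against the mean of the single cytokines to look for an effect beyond either. In edgeR 0 genes passed at 48 h (149 at an unadjusted p under 0.05, 670 with the block) and 0 at 168 h (90, 401 with the block). DESeq2 called 2 and 0, limma-voom 0 and 0, the block 1 and 0. TCEA1P2 was again the blocked call (adjusted p = 0.00715, 0.739 without the block, 7.91e-08 in DESeq2), and RPL15P3 the other in DESeq2 (1.24e-06). Near to passing at 48 h were TMEM230 (0.20), ATP6V1G1 (0.18), PBX3 (0.32), ARPC4-TTLL3 (-0.85) and VCL (-0.45). At 168 h they were RBM4B (0.35), VARS2 (1.69), THYN1 (0.18), SLC15A4 (-0.31), HERC2P3 (-0.56) and CEP85 (-0.39). Without IL17A_F_168h replicate 2 the gene ENSG00000260537 passed (adjusted p = 0.0497), with all of its words in other genes, and without the 8 libraries whose numbers disagree GTF2H2B did (0.00228). Camera called 0 lists at both times, and 5 at 48 h with the block, the interferon list among them as higher with the combination (median 0.17, adjusted p = 7.87e-04, against adjusted p = 0.889 with an estimated correlation). With the block, 0 lists were called with an estimated correlation and 0 by fry.

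The change of the cytokine effect from 48 to 168 h was tested as an interaction. No gene passed in edgeR (161 at an unadjusted p under 0.05, 797 with the block), limma-voom or with the block, and DESeq2 called PEDS1-UBE2V1 (adjusted p = 7.26e-05). H4C15 passed without control_48h replicate 2 (adjusted p = 0.0371) and GTF2H2B without the 8 libraries whose numbers disagree (0.0220). Ribosome-biogenesis genes moved down from 48 to 168 h relative to control (median -0.12, 29 of 35 below 0, camera adjusted p = 0.0313, against adjusted p = 0.996 with an estimated correlation), and the call was lost without replicate 3 (0.992). POLR1B (-0.32 ± 0.25) and POLR1C (-0.23 ± 0.19) were nearest to passing.

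Fold changes of the cytokine comparisons were correlated across the 16224 genes, which are not independent replicates, and set beside data simulated with no cytokine effect, since the comparisons share control libraries. At 48 h Pearson's r was 0.504 for IL-17A with IL-17F (simulated 0.502, covariance 0.0386 against 0.0370), 0.515 for IL-17A with IL17A + IL17F (0.503, 0.0386 against 0.0372) and 0.481 for IL-17F with IL17A + IL17F (0.5, 0.0378 against 0.0370). At 168 h it was 0.488 (0.493, 0.0386 against 0.0371), 0.530 (0.498, 0.0417 against 0.0374) and 0.494 (0.493, 0.0378 against 0.0371). Among genes with a CPM of at least 5, IL-17A with IL17A + IL17F at 168 h reached 0.679 (simulated 0.491, covariance 0.0140 against 0.00897), and at 48 h 0.358 (simulated 0.505). IL-17A with IL-17F stood at 0.565 at 168 h (simulated 0.490) and 0.476 at 48 h (0.507). For IL-17F with IL17A + IL17F the values were 0.585 (0.490) and 0.334 (0.498). Each pair was thus above its simulation at 168 h and below it at 48 h, and the pairs of a time share their control libraries. Between times r was -0.0232 for IL-17A, -0.0782 for IL-17F and 0.0147 for IL17A + IL17F, against simulated values of -9.32e-04, 0.00305 and 1.18e-04. Spearman's rho was 0.378 to 0.564 within a time and -0.128 to 0.00221 between times.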

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

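The tests of the interferon list, of outgrowth of CD8 or NK cells, of shared reads and of thinned depth were chosen only after the result was seen, with the bounds for shared reads and thinned depth set before the values of those tests were.

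The ribosome-biogenesis list stood out because camera called a change of its cytokine effect between the times. It was lower at 168 h than at 48 h relative to control, by a median of -0.12 with 29 of 35 genes below 0 (camera adjusted p = 0.0313), and the difference itself was tested as an interaction. The call was lost with an estimated correlation (adjusted p = 0.996), with fry (0.991) and without replicate 3 (0.992). Of 100 splits of the libraries, the real one included, 96 called at least as many lists as the 1 called here. Chance therefore cannot be excluded. No other explanation was tested for it.

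Interferon-response genes were lower with IL-17A at 48 h (median -0.25) and with IL-17A, IL-17F and IL17A + IL17F at 168 h (-0.42, -0.30 and -0.35), whereas at 48 h IL-17F and IL17A + IL17F were not called (adjusted p = 0.569 and 0.527; IL-17F 0.0155 with the block) and were lower in 2 of 3 runs, the exception with IL-17F being the library apart from its run, IL17F_48h replicate 2 (0.14); all 4 calls were lost with an estimated correlation (0.898 to 0.997) and with fry (0.9754 to 0.9989). A difference in depth is argued against as the whole cause, since the control total of a run differed from the mean of its cytokine libraries by at most 6.35%. A wrong label at 168 h cannot be told apart from an effect, because only 1 run there has agreeing numbers (-0.438), and the run with the largest difference (-0.762) is 1 of the 2 whose numbers disagree. Variation between libraries of a run cannot be told apart either, because the 64 exchanges of the control label within runs are too few for 35 lists (adjusted p = 0.851 at 168 h, unadjusted p = 0.266 at 48 h). An effect of the cytokines stays open. In the run of the largest difference, the control library lay apart from its 3 others (chi-square per degree of freedom 14.65 to 20.15, against 6.35 to 8.77 among those). Chemokine and homing receptors were lower there too (-0.495, -0.259 and -0.266). Without that run the camera call at 168 h was lost with IL-17F (adjusted p = 0.246). It was kept with IL-17A (0.00215), IL17A + IL17F (0.0162) and in the mean (0.00142), comparisons that share their control libraries. In runs 2 and 3 the list stood at 0.0704 and -0.672 with IL-17A, and at -0.0162 and -0.475 with IL17A + IL17F. The kept calls thus rest mainly on run 3, and camera with the preset correlation also calls lists in groupings that follow no treatment.

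Beside EPSTI1, 7 genes passed in a cytokine comparison under at least 1 other setting but not in the model of all libraries: PEDS1-UBE2V1, RPL15P3, TCEA1P2, GUSBP9, GTF2H2B, H4C15 and ENSG00000260537. Reads shared with near-identical or overlapping genes are a candidate explanation, since 7 of the 7 have 89.2% to 100% of their 31-base words in another gene, against 7.5% of 200 random genes with at least 50%. No biological explanation was tested for them. EPSTI1, lower at 168 h with the run block, shares 0% of its words, which argues against shared reads for this gene. Its fold change at 168 h moved from -0.71 ± 0.29 without the block to -0.68 ± 0.11 with it, so the call came with the smaller error.

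GNLY, GZMK and FGFBP2 rose at 168 h in the control cells, by 4.30, 4.34 and 4.20. Outgrowth of CD8 or NK cells left by the sort for CD4+ CD25- CD45RO+ cells cannot be excluded. Outgrowth alone would need about as large a rise in markers that CD4 cells lack. A marker that CD4 cells also express could hide a rise in a minor population. CD8A and CD8B reached 2.03 and 5.77 CPM beside 485 for CD4. Most other markers of these cells moved less than the 3 genes. The 10 with at least 1 CPM had a median log2 fold change of 0.892 ± 1.41 (SD), with KIR3DL2 (-0.332) and FCGR3A (-0.378) below 0. KLRC2 (4.47) is an exception, and of the 18 genes of that list GNLY and KLRD1 are also in the cytotoxic list, which CD4 T cells can express. At least 100.8% of the 3 fold changes remained after thinning. CPM is relative to the library total, so thinning could hardly have given another result, and nothing is drawn from it about depth. A change within the CD4 cells with time stays open as well.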

How the results depend on the processing

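Chosen only after the result was seen were the tests with a block joining runs of both times, without replicate 3 of all 8 groups, without IL17F_48h replicate 2, with the 48 h libraries thinned, and the within-run permutation. All other alternatives were fixed before the data were examined. Of 490 alternative values of the main counts and correlations, 392 stayed in the same range. Named genes had 8718 alternatives, of which 8628 kept the side of the threshold, 76 lost the call, 14 gained it and 0 reversed. Among the 8628 were 179 fold changes that did not pass and changed sign. Lists had 332 alternatives, of which 219 kept the call, 113 lost it and 0 reversed.

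The time effect kept its counts within 1.5 times except as follows. A minimum absolute log2 fold change of 1 left 3514 genes in control, 3609 with IL-17A, 4089 with IL-17F, 3965 with IL17A + IL17F and 4525 in the mean, by construction. Without the 8 libraries whose numbers disagree, 3969, 4427, 4696 and 4803 genes passed, of which 3714, 4091, 4382 and 4485 were also called with all libraries; this leaves a single library per group at 168 h, assumed to vary like the other groups. Without single libraries the counts were 5908 to 6379 in control, 5946 to 6676 with IL-17A, 6432 to 7355 with IL-17F, 6230 to 7122 with IL17A + IL17F and 11619 to 11824 in the mean. Across all alternatives the median log2 fold change of all genes lay between -0.0049 and 0.0765. Time calls lost most often were CBS, KLF2 outside the control cells, and IL17A and IL17RC in the mean. In the control cells, removal of replicate 3 of all groups also ended the calls of PGAM1 (adjusted p = 0.0728), TNFAIP2 (0.0571) and OSM (0.0840), and removal of those with disagreeing numbers that of HYOU1 (0.124). The cause was not tested.

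For cytokine against control, DESeq2 called 2 genes with IL-17A, 2 with IL-17F and 2 with IL17A + IL17F at 48 h, 1 with IL-17A at 168 h, 1 in the mean at 48 h, 2 for the combination against single cytokines at 48 h and 1 in the interaction, where edgeR called 0. The run block called 1 gene with IL17A + IL17F at 48 h, 2 with IL-17A at 168 h, 1 in the mean at 168 h and 1 for the combination at 48 h, and changed no other call of a named gene in these comparisons. Without the 8 libraries whose numbers disagree, 1 gene passed with IL-17F, 1 in the mean and 1 for the combination at 168 h, and 1 in the interaction. Without single libraries the counts were 0 to 1 for IL-17A, IL17A + IL17F and the mean at 48 h, for the interaction, and at 168 h for IL-17A, IL-17A against IL-17F and the combination; they were 0 to 0 for IL-17F at both times, IL-17A against IL-17F and the combination at 48 h, and IL17A + IL17F and the mean at 168 h.

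Calls of lists depended on the correlation between genes. With an estimated correlation 0 lists were called in each of the 18 comparisons. Fry called 21, 22, 23, 21 and 33 lists for time in control, IL-17A, IL-17F, IL17A + IL17F and the mean, and 0 in each cytokine comparison. The run block called 1 list with IL-17F at 48 h, 1 in the mean at 48 h, 10 with IL-17A, 6 with IL-17F, 4 with IL17A + IL17F and 4 in the mean at 168 h, 13 for IL-17A against IL-17F at 168 h, 5 for the combination at 48 h and 4 in the interaction. Without 1 replicate the counts for time were 7 to 13 in control, 6 to 13 with IL-17A, 8 to 13 with IL-17F, 7 to 12 with IL17A + IL17F and 9 to 12 in the mean. At 48 h they were 1 to 2 with IL-17A, 0 to 2 with IL-17F, 0 to 2 with IL17A + IL17F, 0 to 3 in the mean, 0 to 1 for IL-17A against IL-17F and 0 to 2 for the combination. At 168 h they were 1 to 5, 2 to 4, 1 to 3, 1 to 4, 2 to 8 and 0 to 1 in the same order, and 0 to 3 in the interaction.

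Among genes with an average CPM of at least 5, the correlations of IL17A + IL17F with IL-17A and IL-17F were 0.358 and 0.334 at 48 h and 0.679 and 0.585 at 168 h, and those between times 0.0509 for IL-17A and -0.210 for IL-17F. With the run block the correlation between times was -0.0747 for IL-17A and -0.0153 for IL17A + IL17F. The cause was not tested.

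The 48 h libraries, thinned to the smallest total at 168 h, gave 6972 genes for time in control, against 7137. The greater depth at 48 h thus added few calls there. Thinning was not tried in the cytokine comparisons, so it does not show whether depth limited them. The spread between runs limited the cytokine comparisons, where the median SE for IL-17A at 48 h, among genes with a log2 CPM of at least 4, was 0.17 without and 0.09 with the block.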

Other observations

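The test of other splits of IL-17A against control at 168 h was chosen only after the result was seen, and the other split tests before.

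Other splits of the same libraries show how far the counts exceed what an arbitrary grouping gives. For time in the mean of the conditions 1 of 100 splits of single libraries, the real one, reached 11796 genes and the highest other gave 3. Libraries of a run correlate at 0.479 to 0.705 and each run lies at 1 time, so the 6 runs, with 10 splits, are too few for a share under 0.05. Within a single condition, 10 splits of 6 libraries are too few for a share under 0.05. There the real split gave 7137 genes in control, 7168 with IL-17A, 7718 with IL-17F and 7664 with IL17A + IL17F, each reached by 1 of 10 splits, and the highest other gave 0. For lists called by camera, chance cannot be excluded for time in the mean, where 43 of 100 splits reached the 10 lists and the highest other gave 19. Within a condition the splits are again too few, with 6 of 10 splits reaching the 10 lists in control (highest other 17), 6 the 8 with IL-17A (15), 5 the 9 with IL-17F (14) and 5 the 9 with IL17A + IL17F (15).

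For each cytokine against control and for IL-17A against IL-17F, at both times, the 10 splits are too few for a share under 0.05. The real count of 0 genes was reached by 10 of 10 splits, and the highest other gave 1 gene for IL-17A at 48 h and 0 in the 7 other comparisons. Lists at 48 h were 1 with IL-17A (9 splits, highest other 20), 0 with IL-17F (10 splits, 17), 0 with IL17A + IL17F (10 splits, 22) and 1 for IL-17A against IL-17F (8 splits, 17). Lists at 168 h were 1 with IL-17A (10 splits, 13), 2 with IL-17F (9 splits, 17), 1 with IL17A + IL17F (9 splits, 13) and 6 for IL-17A against IL-17F (5 splits, 13). Splits that part all 3 runs, as the real one does, gave 0 to 3 lists, and those that part fewer gave 2 to 22. IL-17A against IL-17F at 168 h, with 6 lists, lay above the 0 to 1 of its 3 other splits of that kind.

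Where the real count was 0, each split reaches it and the test decides nothing. In the mean of the cytokines against control, 100 of 100 splits reached the 0 genes at 48 h (highest other 2369) and 100 of 100 at 168 h (1445), and chance cannot be excluded for the 2 lists at each time, reached by 81 and 87 of 100 (highest other 23 and 17). For the combination against single cytokines, 84 of 84 splits reached the 0 genes at 48 h (2643) and 84 of 84 at 168 h (1924), and 84 and 84 the 0 lists (23 and 15). For the interaction 100 of 100 splits reached 0 genes (1297) and chance cannot be excluded for the 1 list, reached by 96 of 100 (21). Splits that call many genes point to a structure of the samples. In the comparisons within a time, those with the most genes take all 3 libraries of the smaller side from 1 run, whereas splits that take them from 3 runs, as the real ones do, gave 0 to 1 genes and 0 to 6 lists. With the run as a block the real splits gave 0 and 1 genes for the mean of the cytokines and 1 and 0 for the combination, at 48 and 168 h, and 0 for the interaction. Camera with the preset correlation therefore calls lists in groupings that follow no treatment.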
